A study of Homo sapiens with 5 samples.

How the data were processed

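RNA-seq libraries of MDA-MB-231 clones were compared, 2 labelled wild type for ST6GAL1 (ST6WT) and 3 labelled knockout (ST6KO). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a TruSeq total RNA kit after lentiviral infection. Groups and replicate numbers were taken from the labels. The series design describes clones from sorted single cells but does not say how the clones map to independent editing events, so p-values measure only the spread between these samples.

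The authors deposited 1 file per library with whole-number read counts per Ensembl gene, not normalised. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 were used and the builds hg19 and mm10 were named, without a stated role or order. The strand setting, the annotation and any filter on rows are not given in the sources used here. All 15 mitochondrial genes listed were at 0 in every library, so that measure of RNA quality could not be used. Abundant nuclear RNAs were used in its place. The 4 most abundant genes took between 5.23% and 6.41% of the counts per library.

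Gene symbols were matched by Ensembl ID for 24558 of the 35700 genes, and for 14126 of the genes tested. Chromosomes came from GENCODE 29, whose build differs from hg19, so no positions are printed. Symbols of the gene lists were matched for 1019 of 1043 entries.

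The main test was edgeR 4.0.16 in R 4.3.3, with its default filter on low counts, TMM normalisation, the quasi-likelihood test, 2-sided p-values and Benjamini-Hochberg adjustment over 14607 genes. All 5 libraries entered without a block. Gene lists, 41 in number, were written before the data were examined, and the 38 with at least 4 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Each was also tested with an estimated correlation and with fry. Of the 10 lists called by camera, none was called with an estimated correlation (smallest adjusted p = 0.294) or by fry's directional test (smallest 0.188), while fry's test for changes in either direction called 18 lists.

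The rule for named genes was fixed before the data were examined: ST6GAL1, the 10 highest and 10 lowest log2 fold changes among called genes with a log2 mean CPM of at least 1 and no overlap between groups, up to 3 called members per list, and 12 further genes of interest. As the main test called none, this rule left only the fixed genes. The same rule was therefore applied to DESeq2 1.42.0, first to its calls alone and then, for the 20 highest and lowest genes, to those also called by edgeR without ST6KO replicate 2, since DESeq2 made more false calls in simulated data. Members of lists were taken from DESeq2's calls. These choices, including the library left out, were made after the values were seen. CDH11, TNFSF10 and other list members follow the list part of the rule. Markers in single libraries were named after their counts were seen. Some genes are not reported here; they stay in the tests over all genes and lists and are left out of the marker tests of the closing section.

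The tests were tried on simulated counts with the means, depths and dispersions of these libraries and 200 changed genes. For this comparison, edgeR over 14352 genes recovered 8 of 100 changes of 2-fold and 88 of 100 of 8-fold, with 105 calls of which 8.57% were false. DESeq2 over 14607 genes recovered 26 and 94 of 100, with 180 calls of which 33.3% were false. Both results rest on a single draw in which genes varied independently and the changed genes came from those with higher counts. EdgeR called 0 genes in the real libraries, so the simulated recovery and false shares may not carry over to them. A gene list raised by 2-fold was called by camera, and 0 unchanged lists were. The simulated counts did not take over the correlation between genes of a list. In the real data, its estimates for the lists called by camera ran from 0.026 (luminal markers) to 0.564 (ribosomal proteins), above the preset value. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes.

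For genes with 10 or fewer pooled counts in a group, the ratio of pooled counts is given with an exact 95% interval, or, at 0 counts, a lower bound from a floor of 3 counts over the group. These intervals and floors cover counting error only. Alternatives were other size factors (RLE, total counts), DESeq2, no filter and a stricter filter, each library left out in turn and the replicate number as a block. Limma-voom, DESeq2 without ST6KO replicate 2, and DESeq2 with each library's chromosome medians removed through its normalisation factors were added after the data were seen. The last replaced a test of the share of each fold change left after subtracting a chromosome's median, whose outcome the size of the called changes fixed. That size also largely sets how many calls outlast the removal. A test of copy number from the same medians was dropped, as it restated them. Figures were drawn with matplotlib.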

Results

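RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line, after lentiviral delivery of a CRISPR/Cas9 guide against ST6GAL1. ST6GAL1 is the Golgi enzyme that adds α2,6-linked sialic acid to the ends of N-glycans. Per the series design, single cells were sorted to give clones, and the 5 libraries comprised 2 from clones that kept the gene (ST6WT) and 3 from knockout clones (ST6KO). The deposited counts covered 35700 genes, of which 22271 had a count in at least 1 library. Total counts ranged from 14523577 to 15532101 in ST6WT and from 14746959 to 18625304 in ST6KO. Levels are given below as normalised CPM, with the SD over n = 2 ST6WT and n = 3 ST6KO libraries. Unless stated otherwise, normalised CPM is the read count scaled to the library total after correction by its TMM factor.

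The comparison of ST6KO with ST6WT asked how the transcriptome differs between clones without and with the enzyme. ST6GAL1 itself (ENSG00000073849, chromosome 3) was measured at 38.1 and 35.4 CPM in the ST6WT libraries and at 0.66, 5.77 and 0.25 CPM in ST6KO replicates 1, 2 and 3. The counts behind these values were 587 and 506 against 12, 90 and 4. The log2 fold change was −4.05 ± 1.09 (SE) with an adjusted p of 0.222 by edgeR's quasi-likelihood test, and −4.09 ± 1.05 with an adjusted p of 0.00373 by DESeq2. ST6KO replicate 2 decided this call: without it, edgeR gave −6.28 ± 0.42 and an adjusted p of 0.00311. With each library's chromosome medians removed, DESeq2 gave −4.23 ± 1.48 and an adjusted p of 0.0764, as it then used the gene's own, larger dispersion. ST6GAL2, the other enzyme that forms the same linkage, had 0 counts in every library, which allows up to 3 counts per library.

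**Figure D1:**
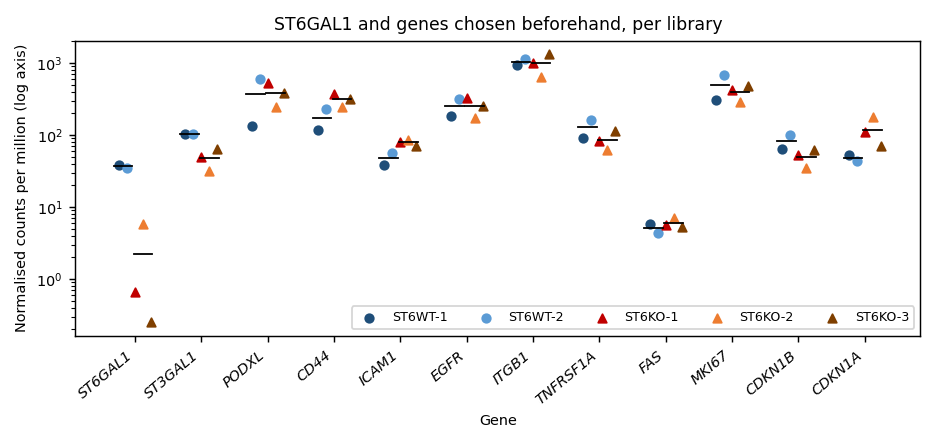
Normalised CPM (log axis) of ST6GAL1 and of 11 genes chosen before the data were examined, with 1 point per library (circles, ST6WT; triangles, ST6KO) and black lines at the group means. ST6GAL1 lay at 35.4 CPM or above in both ST6WT libraries and at 5.77 CPM or below in the ST6KO libraries.

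Several genes with clear expression in both ST6WT libraries were nearly silent in all 3 ST6KO libraries. AGR2, a protein disulfide isomerase of secretory epithelia, was at 36.2 ± 5.97 CPM in ST6WT and 0.101 ± 0.0965 CPM in ST6KO, and its pooled counts were 354-fold lower (95% interval 151 to 1094, and 623-fold without ST6KO replicate 2). The trefoil peptide genes TFF2 and TFF3, both on chromosome 21, were at 26.8 ± 6.22 and 21.9 ± 10.7 CPM in ST6WT against 0.22 ± 0.137 and 0.0427 ± 0.074 CPM in ST6KO, where replicate 2 held both counts of TFF3. CDH11, a mesenchymal cadherin, was at 165 ± 22.6 CPM against 2.06 ± 1.43 CPM (log2 fold change −6.36 ± 0.50, DESeq2 adjusted p = 2.82e-33; edgeR gave −6.33, and −7.05 without ST6KO replicate 2). The lymphocyte receptor genes CD96 and SLAMF7 followed the same direction: CD96 had 2011 counts over the ST6WT libraries and 0 in ST6KO, at least 1099-fold lower with a floor of 3 counts over the group, and SLAMF7 had 747 counts against 5. ST6WT replicate 1 held 1694 of the CD96 counts and replicate 2 held 317, and the bound was 358-fold without replicate 1, 1792-fold without replicate 2 and 684-fold without ST6KO replicate 1. The log2 fold change of SLAMF7 by edgeR was −7.86, and −8.57 without ST6KO replicate 3.

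The muscarinic receptor gene CHRM3 was at 17.5 ± 0.387 CPM in ST6WT and 0.168 ± 0.245 CPM in ST6KO, where replicate 2 held 7 of its counts and replicates 1 and 3 held 1 and 0. Its antisense partner CHRM3-AS2 had 172 counts (142 in ST6WT replicate 1, 30 in replicate 2) against 1, but the strand setting of the counting is not given in the sources used here, so reads of this pair may not be separated. The BMP antagonist gene CHRDL1 had 877 counts in ST6WT against 8, a 180-fold lower ratio (95% interval 90.8 to 418, and 98-fold without ST6WT replicate 1). NALF1 and SDR16C5 had 223 and 168 counts in ST6WT and 0 in ST6KO, which makes them at least 122-fold and 91.8-fold lower, or 75.8-fold and 57.1-fold without ST6KO replicate 1, where fewer reads are pooled.

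Genes higher in ST6KO included TP53I11, which was at 0.3 ± 0.127 CPM in ST6WT and 10.8 ± 1.05 CPM in ST6KO, with a 36-fold ratio of pooled counts (95% interval 18.8 to 79.1). ALOX5, the 5-lipoxygenase of leukotriene synthesis, had 10 counts in ST6WT and 572 in ST6KO, a 34.9-fold ratio (95% interval 18.8 to 73.1). BCHE (butyrylcholinesterase) was at 13.5, 2.69 and 18.3 CPM in ST6KO replicates 1, 2 and 3 and below 0.2 CPM in ST6WT. HKDC1, a hexokinase-family gene, was at 1.54 ± 0.301 CPM against 28.2 ± 19.9 CPM, and CST7, which encodes cystatin F, at 1.87 ± 0.811 CPM against 30.3 ± 20.6 CPM. The non-coding RNA SNHG18 had 6 counts against 270, RASD2 5 against 155, and the antiproliferative gene BTG2 was at 0.367 ± 0.124 CPM against 6.15 ± 6.06 CPM. ST6KO replicates 1, 2 and 3 held 41, 205 and 48 counts of BTG2, and its log2 fold change by edgeR was 4.03, or 2.82 without replicate 2. That of HKDC1 was 4.19, or 3.50 without ST6KO replicate 1, and that of SNHG18 4.70, or 5.32 without ST6WT replicate 2.

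For a pair of genes in the higher group, the difference came from ST6KO replicates 1 and 3. FSTL5 was at 28.6 and 30.5 CPM in replicates 1 and 3, but at 0.13 CPM in replicate 2 and 0.06 and 0 CPM in ST6WT. ACKR3, a scavenging receptor for the chemokine CXCL12, was at 4.08 and 5.74 CPM in replicates 1 and 3, at 0.19 CPM in replicate 2, and at 0.06 and 0.14 CPM in ST6WT.

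The 20 genes shown in the plot of the most different genes had DESeq2 adjusted p-values from 1.76e-26 to 0.0228 and edgeR adjusted p-values from 0.00275 to 0.0401 without ST6KO replicate 2. With all 5 libraries, edgeR gave them adjusted p-values from 0.0582 to 0.261, above the threshold.

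**Figure D2:**
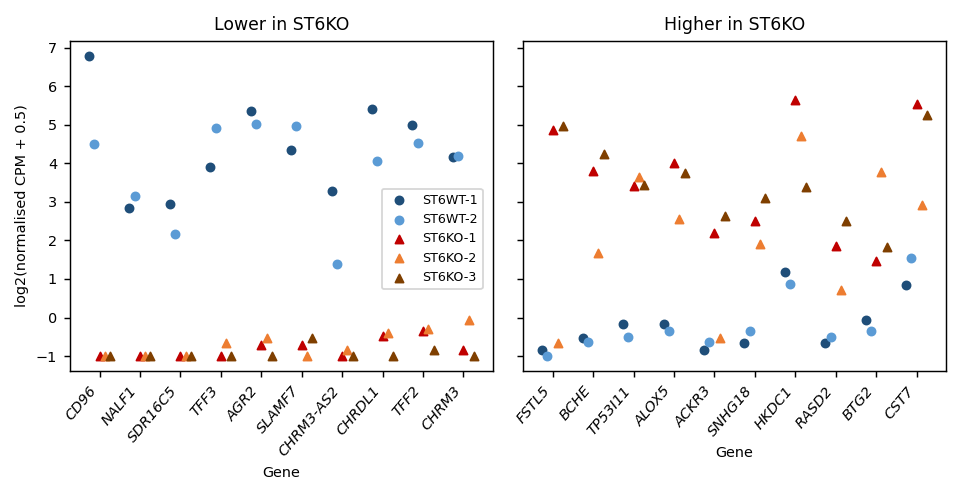
The 10 genes with the lowest and the 10 with the highest log2 fold change among genes called by DESeq2 on all 5 libraries and by edgeR without ST6KO replicate 2, as log2(normalised CPM + 0.5) per library. FSTL5 and ACKR3 in ST6KO replicate 2 lay at 0.13 and 0.19 CPM, near the ST6WT libraries.

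Across the 14607 genes tested, edgeR's quasi-likelihood test on all 5 libraries called 0 genes at an adjusted p of 0.05 (smallest 0.0582), while 1974 genes had an unadjusted p under 0.05 where 730 are expected by chance. DESeq2 was run without edgeR's filter on low counts, with a p-value for 22214 genes, and called 493 higher and 398 lower. Limma-voom called 1 higher (HLA-B) and 5 lower (AGR2, CDH11, TFF2, SDR16C5 and NALF1). EdgeR without ST6KO replicate 2 called 347 higher and 333 lower, where leaving out ST6KO replicate 1 or 3 gave 0. Of these, 382 genes were called both by DESeq2 and by edgeR without that replicate, 213 higher and 169 lower, with 0 in opposite directions. Of 89 named genes called by DESeq2, edgeR without that replicate called 56, DESeq2 without it 83 and DESeq2 with each library's chromosome medians removed 77. The count of 56 was partly fixed in advance, as the 20 highest and lowest genes were named for being called by edgeR without that replicate. Over the 14218 genes with an adjusted p in both, where DESeq2 called 429 higher and 384 lower and edgeR 347 and 317, independent lists would share 10.5 and 8.56 genes, but the calls rest on 4 shared libraries, which adds to the overlap. In data simulated for this comparison over 14607 genes, 33.3% of DESeq2's calls were false, against 8.57% of edgeR's calls over 14352 genes. EdgeR made 105 calls in those data and 0 in the real libraries. The simulated genes varied independently in a single draw, so these shares may not hold for the real calls. The calls without ST6KO replicate 2 rest on ST6KO replicates 1 and 3, which correlated at 0.987 over genes against 0.96 for the ST6WT pair. The labels do not say whether these 2 come from independent edits or from the same clone. The groups did not overlap for 4646 genes (31.8%, where chance gives 20%). Genes do not vary independently, and a split of the libraries that mixes the groups gave 1971 genes at an unadjusted p under 0.05 by edgeR. The excess over chance therefore does not by itself show a difference between the groups.

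Among the sialyltransferases other than ST6GAL1, 14 of 19 were tested, and none was called higher by DESeq2 and 2 were called lower. ST3GAL1, which caps O-glycans with α2,3-linked sialic acid, was at 104 ± 1.15 CPM in ST6WT and 48.5 ± 16.6 CPM in ST6KO (log2 fold change −1.11 ± 0.36, DESeq2 adjusted p = 0.0414, or −0.99 ± 0.34 and 0.0744 with chromosome medians removed). ST3GAL6 was at 40.5 ± 23.9 against 13.8 ± 3.94 CPM (−1.58 ± 0.47, DESeq2 adjusted p = 0.0208), and by edgeR it was −1.56, or −0.78 without ST6WT replicate 1. Of 11 tested genes of sialic acid synthesis and sialidases, 2 were called higher and 0 lower by DESeq2, and edgeR's p-values adjusted over the list alone gave the same numbers. These were the lysosomal sialidase NEU1, at 56.3 ± 3.31 against 199 ± 44.1 CPM (1.81 ± 0.28, DESeq2 adjusted p = 4.45e-08), and the lysosomal sialic acid exporter SLC17A5, at 58.8 ± 5.34 against 132 ± 26.9 CPM (1.15 ± 0.27, DESeq2 adjusted p = 0.00149, or 0.93 ± 0.31 and 0.0505 with chromosome medians removed).

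Of 22 N-glycan processing genes, DESeq2 called 3 higher and 1 lower. The Golgi mannosidase MAN2A1 was at 239 ± 43.2 CPM in ST6WT and 118 ± 1.6 CPM in ST6KO, the branching enzyme MGAT4A at 8.03 ± 3.25 and 21.8 ± 3.13 CPM, and the GDP-fucose transporter SLC35C1 at 12.9 ± 1.57 and 24.1 ± 2.22 CPM. GALNT6 was the 1 of 17 mucin-type O-glycan enzymes called, at 106 ± 39.8 against 37.3 ± 5.09 CPM. None of these glycan lists shifted as a set by camera, with adjusted p of 0.725 for sialyltransferases, 0.139 for sialic acid genes, 0.138 for N-glycan genes (0.0254 without ST6WT replicate 1) and 0.66 for O-glycan enzymes. For the sialyltransferases the median log2 fold change was 0.11 and the mean −0.03.

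Among antigen presentation genes, DESeq2 called 6 of 21 tested members higher and 1 lower, as did edgeR's p-values adjusted over the list alone (0 over all genes). HLA-B, a class I heavy chain, was at 154 ± 5.31 CPM in ST6WT and 647 ± 82.6 CPM in ST6KO (2.05 ± 0.19, DESeq2 adjusted p = 8.09e-23). HLA-C and HLA-F were at 105 ± 4.14 and 2.46 ± 0.0799 CPM against 271 ± 38.9 and 12 ± 3.53 CPM; class I genes resemble each other closely, so how reads divide between them is uncertain. The list was called by camera with a preset correlation (adjusted p = 0.000629), and not with an estimated correlation (adjusted p = 0.73) or without ST6WT replicate 2 (adjusted p = 0.0966).

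Interferon-stimulated genes showed 9 of 42 members higher and 0 lower by DESeq2, and 2 higher by edgeR adjusted over the list alone. The viral RNA sensor IFIH1 was at 9.85 ± 0.203 against 29 ± 4.82 CPM, and RSAD2 (viperin) at 0.669 ± 0.156 against 7.78 ± 3.25 CPM. Camera called the list with an adjusted p of 2.15e-05, or 0.73 with an estimated correlation. Relative to the ST6WT mean, the list's median stood at 0.69 and 0.84 (log2) in ST6KO replicates 1 and 3 and at 0.04 in replicate 2, within the −0.29 and 0.29 of the ST6WT libraries. NF-kB targets and cytokines had 3 of 28 members called higher and 0 lower by DESeq2, among them IL32, at 0.512 ± 0.265 against 5.99 ± 2.51 CPM, and IL6, at 18.6 ± 6.44 against 98.9 ± 76.1 CPM. DESeq2 did not call IL6 without ST6KO replicate 2 (adjusted p = 0.0866). Their log2 fold changes by edgeR were 3.53, or 4.17 without ST6WT replicate 2, and 2.41, or 1.57 without ST6KO replicate 1. The camera adjusted p of this list was 0.00844, or 0.73 with an estimated correlation, and 0.284 without ST6WT replicate 2, and its median was 0.71, 0.53 and 0.05 in ST6KO replicates 1, 2 and 3 against 0.06 and −0.06 in ST6WT. TNFSF10, the death ligand TRAIL, was at 10.4 ± 3.77 CPM in ST6WT and 75.2 ± 9.62 CPM in ST6KO (2.84 ± 0.32, DESeq2 adjusted p = 2.46e-15).

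Among adhesion genes, 3 of 15 integrins were called lower and 1 higher by DESeq2. The collagen-binding subunits ITGA10, ITGA1 and ITGA2 were at 94.7 ± 7.22, 83.6 ± 21.6 and 816 ± 535 CPM in ST6WT and at 10.6 ± 5.02, 32.7 ± 3.31 and 211 ± 42.4 CPM in ST6KO. ITGA2 had a log2 fold change of −1.95 by edgeR, or −1.05 without ST6WT replicate 1. Camera gave the integrins an adjusted p of 0.00794, or 0.73 with an estimated correlation, 0.153 without ST6KO replicate 2 and 0.124 without ST6WT replicate 2, with medians of −0.03, −1.18 and −0.40 in ST6KO replicates 1, 2 and 3 and of −0.12 and 0.12 in ST6WT. The tested cadherin and junction genes numbered 22, with CDH11, the tight junction gene F11R and the desmosomal gene PKP2 (adjusted p = 0.13 with chromosome medians removed) lower and 1 member higher by DESeq2 (camera adjusted p = 0.0844, or 0.00458 without ST6WT replicate 1, 0.02 without ST6KO replicate 2 and 0.049 without ST6KO replicate 3). Of the genes tied to tumour cell clusters, CD44 was at 175 ± 82.3 against 312 ± 65.6 CPM (DESeq2 adjusted p = 0.222, and 0.0481 on ST6KO replicates 1 and 3 only), ICAM1 at 48 ± 12.9 against 78.8 ± 7.27 CPM (0.0915) and PODXL at 369 ± 333 against 384 ± 141 CPM (0.988). L1CAM, a neural adhesion molecule linked to invasion, was the member called, at 9.76 ± 3.98 against 112 ± 57 CPM (3.51 ± 0.55, DESeq2 adjusted p = 3.99e-08). By edgeR the log2 fold change of CD44 was 0.83, or 0.42 without ST6WT replicate 1 and 1.42 without ST6WT replicate 2. The cluster list had a camera adjusted p of 0.0521, or 0.00684 without ST6KO replicate 2, 0.000481 without ST6WT replicate 2, 0.0425 with total counts only and 0.0144 with no filter.

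In the matrix and mesenchymal lists, members moved both ways. COL13A1, the hyaluronan synthase gene HAS2 and the laminin gene LAMA3 were lower, at 374 ± 50.1, 37.5 ± 15.6 and 146 ± 15.3 CPM in ST6WT against 136 ± 7.67, 5.37 ± 2.26 and 84.1 ± 6.68 CPM in ST6KO, though LAMA3 was not called with chromosome medians removed (adjusted p = 0.378). Among the mesenchymal markers, DESeq2 called 3 higher and 1 lower of 21. SNAI2, a repressor of epithelial genes, was at 11.5 ± 5.17 against 54.8 ± 21.2 CPM, and the intermediate filament gene VIM at 2376 ± 9 against 1252 ± 271 CPM. Neither list was called by camera on all 5 libraries (adjusted p = 0.237 for matrix genes, whose median was −0.19 and mean 0.39, and 0.23 for mesenchymal markers), but matrix genes were without ST6WT replicate 1 (0.0118, lower) and mesenchymal markers without ST6KO replicate 3 (0.0289, higher). The 5 tested fibroblast markers had medians of 1.45, 0.08 and 2.24 in ST6KO replicates 1, 2 and 3 and of −0.49 and 0.49 in ST6WT (camera adjusted p = 0.237, or 0.000908 without ST6KO replicate 2).

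The known receptor substrates of ST6GAL1 showed no call among 10 tested genes, and camera gave the list an adjusted p of 0.684, or 0.0142 without ST6WT replicate 1. EGFR was at 250 ± 90.2 CPM in ST6WT and 250 ± 74.7 CPM in ST6KO, FAS at 5.05 ± 1.02 and 6 ± 0.986 CPM, TNFRSF1A at 127 ± 51.1 and 86.2 ± 27.2 CPM, and ITGB1 at 1038 ± 120 and 998 ± 342 CPM. The log2 fold changes were −0.01 ± 0.38, 0.23 ± 0.40, −0.58 ± 0.40 and −0.07 ± 0.35 by DESeq2, so changes of this size could not be told from the spread between libraries.

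Within the immediate early and AP-1 list, DESeq2 called 6 of 29 members lower and 0 higher in ST6KO, and edgeR adjusted over the list alone called 3 lower. The ERK phosphatase DUSP6 was at 822 ± 58.1 against 247 ± 90.3 CPM (−1.75 ± 0.38, DESeq2 adjusted p = 0.000287), DUSP4 at 1051 ± 247 against 289 ± 111 CPM, and the transcription factor ETV4 at 79.4 ± 6.87 against 39 ± 6.15 CPM. The list's camera adjusted p was 0.0004, or 0.73 with an estimated correlation, and its median in ST6KO replicate 1 was 0.29 above the ST6WT mean, opposite to −0.61 and −0.87 in replicates 2 and 3. The call was absent without ST6KO replicate 2 (adjusted p = 0.0814) or without ST6WT replicate 2 (0.0966). JAG1, a Notch ligand, was at 268 ± 20.2 against 84 ± 21.2 CPM.

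Of 44 G1/S and replication genes, 34 had a lower and 10 a higher log2 fold change, with a median of −0.25 (camera adjusted p = 0.00101, or 0.73 with an estimated correlation, and 0.124 without ST6WT replicate 2). The list's median was −0.30, 0.00 and −0.51 in ST6KO replicates 1, 2 and 3 and −0.10 and 0.10 in ST6WT. DESeq2 called PRIM1, the small primase subunit, at 55 ± 8.33 against 26.6 ± 8.25 CPM, and RFC4, a subunit of the clamp loader, at 89.2 ± 0.609 against 63 ± 2.99 CPM. PRIM1 was not called with chromosome medians removed (adjusted p = 0.132), nor RFC4 without ST6KO replicate 2 (0.108). All 12 tested replication-dependent histone genes had a lower log2 fold change, and DESeq2 called 5 of them. Camera gave this list an adjusted p of 1.69e-07, or 0.73 with an estimated correlation. H4C16 was at 136 ± 35.9 against 59.7 ± 3.97 CPM and H2BC21 at 232 ± 5.21 against 128 ± 21.5 CPM, though near-identical histone copies make the division of reads uncertain. No member of the G2/M list was called among 44 (camera adjusted p = 0.27, or 0.000179 without ST6WT replicate 1 and 0.00963 without ST6KO replicate 3), and MKI67 was at 492 ± 267 against 396 ± 101 CPM.

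CDK inhibitor and quiescence genes were not called as a list (camera adjusted p = 0.958). CDKN1A, the p21 inhibitor, was at 48.4 ± 6.25 against 119 ± 54 CPM (1.27 ± 0.41, DESeq2 adjusted p = 0.0345, or 1.07 ± 0.39 and 0.0984 with chromosome medians removed, and 0.103 by edgeR without ST6KO replicate 2), and CDKN1B, which encodes p27, at 81.6 ± 25 against 49.7 ± 13.6 CPM (DESeq2 adjusted p = 0.292). Cytosolic ribosomal protein genes had 67 of 75 members with a lower log2 fold change (median −0.22, camera adjusted p = 0.000118). That call was absent with an estimated correlation (adjusted p = 0.73) and without ST6WT replicate 1 (adjusted p = 0.317), and the medians were −0.35, 0.00 and −0.28 in ST6KO replicates 1, 2 and 3 and 0.19 and −0.19 in ST6WT. Cholesterol biosynthesis genes had 20 of 25 members with a higher log2 fold change, and DESeq2 called SQLE, EBP (not with chromosome medians removed, adjusted p = 0.263) and HMGCS1. SQLE, the squalene epoxidase gene, was at 32.7 ± 17.5 against 111 ± 2.44 CPM (1.76 by edgeR, or 2.44 without ST6WT replicate 2). The camera adjusted p for this list was 0.00164, or 0.73 with an estimated correlation, and 0.147 without ST6WT replicate 1, with medians of 0.53, 0.18 and 0.41 in ST6KO replicates 1, 2 and 3 and of −0.18 and 0.18 in ST6WT. ST6WT replicate 1 also had the lowest levels of the nuclear RNAs MALAT1 (2020 CPM, 5185 to 9289 elsewhere) and NEAT1 (340 CPM, 804 to 997 elsewhere), scaled to total counts, while the list of such RNAs was not called (camera adjusted p = 0.371). Of its 7 tested members, DESeq2 called 1 higher and 0 lower. The member called was KCNQ1OT1, at 54.6 ± 19 against 124 ± 20.2 CPM (DESeq2 adjusted p = 0.00751).

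**Figure D3:**
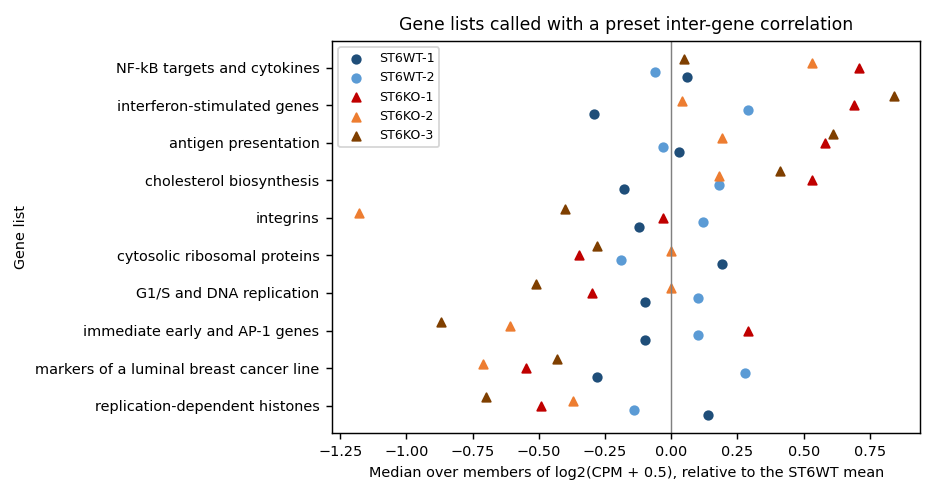
Median over the members of each of the 10 gene lists called by camera with a preset correlation of 0.01, as the difference in log2(CPM + 0.5) from the mean of the 2 ST6WT libraries, with 1 point per library. In the interferon list, ST6KO replicate 2 (0.04) lay between the ST6WT libraries (−0.29 and 0.29).

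Of 16 tested markers of a luminal breast cancer line, DESeq2 called 7 lower and 0 higher in ST6KO (camera adjusted p = 8.14e-11, or 0.294 with an estimated correlation). By edgeR, 12 had a lower and 4 a higher log2 fold change, and without ST6KO replicate 2 it called 6 lower and 1 higher. AGR2 and TFF3, given above, belong to this list, as does SPDEF, a transcription factor of secretory cells, at 28.7 ± 8.29 against 0.91 ± 0.669 CPM (−4.96 by edgeR, or −5.61 without ST6KO replicate 3). The abundant keratins of the list were at 2273 and 4512 counts (KRT8) in ST6WT and at 4314, 2416 and 3641 counts in ST6KO.

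ST6KO replicate 2 stood apart from the other libraries. Its Pearson correlation over genes, in log2 CPM, was 0.923 with replicate 1 and 0.91 with replicate 3, against 0.931 and 0.923 with ST6WT replicates 1 and 2. ST6KO replicates 1 and 3 reached 0.987 with each other and the ST6WT pair 0.96, but ST6WT replicate 1 was also at 0.923 and 0.915 with ST6KO replicates 1 and 3. There were 206 genes at 5 CPM or more in this library and at 0.5 CPM or less in all others, against 20 such genes in ST6WT replicate 1, 1 in ST6WT replicate 2 and 0 in the remaining libraries. Of 13 listed markers of an embryonic kidney packaging line, 7 reached 10 counts in ST6KO replicate 2, and in each other library 0 of the 13 did. They included LIN28B with 1612 counts and HOXD13 with 436, but also NEFH, at the cutoff with 10 counts against 3 to 7 elsewhere. The gene groups above include this library in the ST6KO means. No pair of libraries matched within sampling noise, with a chi-square per degree of freedom of 22.2 or more.

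**Figure D4:**
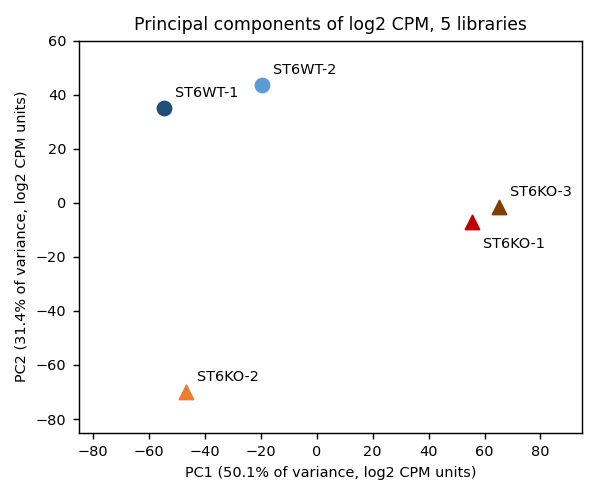
First and second principal components of log2 CPM over 14607 genes, with 50.1% and 31.4% of the variance and 1 point per library. ST6KO replicates 1 and 3 lay at 55.7 and 65.2 on the first component, and ST6KO replicate 2 at −46.6, near ST6WT replicate 1 at −54.6.

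**Figure D5:**
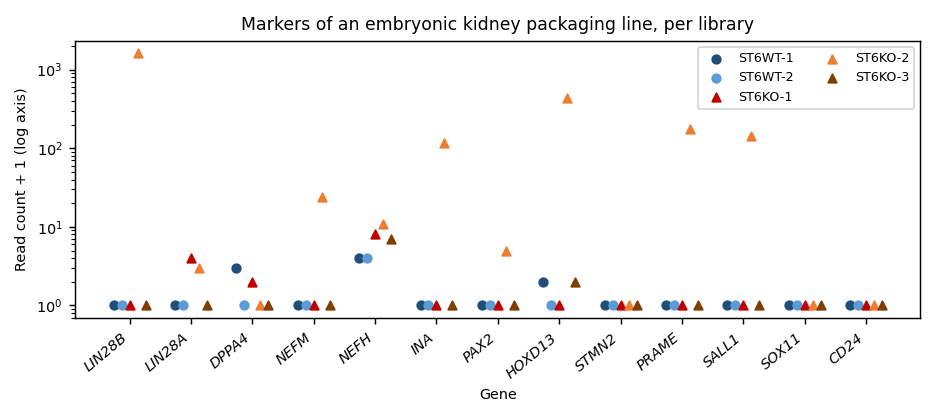
Read counts plus 1 (log axis) of 13 markers of an embryonic kidney packaging line in each library. ST6KO replicate 2 had 1612 counts of LIN28B, 436 of HOXD13, 174 of PRAME, 142 of SALL1 and 115 of INA, and the other libraries had at most 1 count of each.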

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

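All tests in this part were chosen after the values they bear on had been seen. Markers that were too low for testing in most libraries stood above the ST6WT libraries in single ST6KO libraries. ST6KO replicate 2 had 1612 counts of LIN28B, 1044 of DSC3, 436 of HOXD13, 174 of PRAME, 142 of SALL1, 115 of INA, 103 of FOXA1, 35 of COL3A1 and 23 of NEFM, where the ST6WT libraries had at most 3 counts of any of them. ST6KO replicate 1 had 19 counts of KRT17 against at most 1 in ST6WT.

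The first pattern is that ST6KO replicate 2 stands apart from the other 4 libraries. In this library, 283 genes with a count were at 5 CPM or more and at least 8-fold above both ST6WT libraries (median log2 ratio 4.01). Their median in ST6KO replicates 1 and 3 was 0.00 (95% bootstrap interval 0.00 to 0.00). This value partly restates the pattern, which was seen in part from genes at 0.5 CPM or less in all other libraries. Over the 76 of them that passed the filter on low counts, the median in replicates 1 and 3 was 0.14 (−0.19 to 0.79, against 3.52). That argues against loss of ST6GAL1 as a source common to these 76 genes. For the 20 at least 2-fold up in both replicates loss of ST6GAL1 stays open. For another cell line in place of the clone, among 4176 genes steady in the other libraries the lowest ratio in this library was 0.23, and 0 lay below 0.1. The lowest such ratio of ST6KO replicate 3 was 0.07, while 45 genes lay below 0.5 in ST6KO replicate 2, against 0 to 20 elsewhere. Ratios expected of another line were not measured, and genes steady in these libraries may be expressed in other lines too. These ratios therefore do not decide on another line in ST6KO replicate 2. Cells of a packaging line, a usual source of lentivirus, may have contributed, because 7 of 13 listed markers had at least 10 counts there and 0 did elsewhere. Among the 7, NEFH had 10 counts there against 3 to 7 elsewhere, so it hardly sets the library apart. However, STMN2 and SOX11 stayed at 0 counts and PAX2 at 4, and DSC3 and FOXA1 are not on that list. Sorting of single cells would also remove carried-over cells. Packaging-line cells, another cell line and divergence of the clone, which was not tested, stay open.

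The second pattern is the set of secretory genes AGR2, TFF1, TFF3 and SPDEF, at far higher counts in ST6WT. Luminal breast cancer cells in the ST6WT libraries may be a source, though sorting of single cells would remove them too, and 2 of 7 other luminal markers below 10 CPM in every ST6KO library were higher in both ST6WT libraries than in all ST6KO libraries (ERBB3 and, at 4 counts or fewer, PGR), where chance gives 10%. GATA3, with 14 and 39 counts in ST6WT, and EPCAM, with 60 and 106, were at 23 counts or more and 127 or more in ST6KO. Against such cells, ST6WT replicates 1 and 2 had 3 and 2 counts of FOXA1, 3 and 9 of ESR1, 2 and 16 of CDH1 and 0 of AGR3, beside 623 and 458 of AGR2, and FOXA1 and ESR1 were highest in ST6KO replicate 2 (103 and 19). The profile of such cells was not measured here, so these counts do not decide, and luminal cells, clonal differences and the loss of ST6GAL1 cannot be told apart for these genes.

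The third pattern is the number of genes that differ between ST6KO and ST6WT. The real grouping gave 1974 genes at an unadjusted p under 0.05 and the highest of the other splits gave 2567, so 2 of the 10 splits of the 5 libraries into groups of 2 and 3 gave as many, and ST6WT replicate 1 with ST6KO replicate 2 against the rest, which mixes the groups, came just under at 1971; 10 splits are too few for a share under 0.05. The split with 2567 genes, 24 of them called, set ST6KO replicates 1 and 3 against the rest, which points to a structure of the samples, but it also follows the ST6GAL1 level (5.77 CPM in ST6KO replicate 2 against 0.66 and 0.25), and no test separated the 2. After each library's chromosome medians were removed, 598 of 875 genes called by DESeq2 (68.3%) were still called in the same direction. The size of the changes largely set this share. DESeq2 called 340 genes higher and 264 lower by at least 2-fold, while the largest median log2 fold change of a chromosome was 0.43 (X). Whole-chromosome shifts are therefore argued against as the whole account only of such large changes. Shifts of parts of chromosomes were not tested. Among the 277 lost calls the median size of the log2 fold change went from 0.89 to 0.61 (SE 0.26 in each). At least 0.9 of the change was left for 48 of them, ST6GAL1 among them (−4.09 ± 1.05 before, −4.23 ± 1.48 after). The size of a change largely sets this too, so it is no separate evidence against shifts for the 48. Shifts stay open for the other 229.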

How the results depend on the processing

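The alternatives were chosen before the data were examined, except limma-voom, DESeq2 without ST6KO replicate 2 and DESeq2 with chromosome medians removed. The count of 0 called genes held with RLE size factors, total counts only, the stricter filter and the replicate block. DESeq2 called 493 higher and 398 lower genes (340 and 264 by at least 2-fold), and with ST6KO replicates 1 and 3 only, 852 and 756 (557 and 577), and with chromosome medians removed, 357 and 353 (265 and 243). Limma-voom called 1 higher and 5 lower, the same numbers at 2-fold, and no filter called 0 higher and 3 lower. Leaving out each library in turn gave 0 to 347 higher and 0 to 333 lower genes (0 to 314 and 0 to 318 by at least 2-fold); every count above 0 came without ST6KO replicate 2. The cause was not tested.

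ST6GAL1 was lower in every setting. It passed the threshold with DESeq2 (−4.09, adjusted p = 0.00373), with DESeq2 on ST6KO replicates 1 and 3 (−6.29, 3.95e-35) and without ST6KO replicate 2, and log2 fold changes with each library left out ranged from −6.28 to −3.52. Adjusted p over all alternatives ranged from 3.95e-35 to 0.649.

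Of 98 named genes, 4 reversed in some setting, none of them called in any. EGFR (main value 0.00) was 0.01 with total counts, 0.00 with no filter and limma-voom, 0.20 with DESeq2 on ST6KO replicates 1 and 3, and up to 0.42 from a lowest value of −0.33 with libraries left out. ITGB1 was 0.18 with DESeq2 on those replicates, and with libraries left out ranged from −0.32 to 0.17, MKI67 from −0.78 to 0.38 and PODXL from −0.65 to 1.52 (−0.26 by DESeq2 with chromosome medians removed).

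Gene lists called by camera numbered 10, and 0 with an estimated correlation or by fry. For the luminal list the estimated correlation of 0.026 was near the preset 0.01, yet the camera adjusted p went from 8.14e-11 to 0.294. The other called lists had larger estimates, up to 0.564 for ribosomal proteins. The loss of calls therefore need not come from correlation between genes alone, and its cause was not tested. With libraries left out the count ranged from 7 to 17, the highest without ST6WT replicate 1. The replicate numbers share only a name: deviations of same-numbered libraries correlated at −0.21 and −0.27, and the replicate block called 16 lists and 0 genes. Counts near 0 limit the folds of genes silent in a group, and edgeR recovered 8 of 100 simulated 2-fold changes.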

Other observations

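The tests on chromosomes and on ST6KO replicate 2 in this part were chosen after the values were seen. Genes of drug response were among those called by DESeq2 in ST6KO: CYP1B1, a cytochrome that oxidises oestrogens and xenobiotics, was at 30.6 ± 22.7 CPM in ST6WT and 169 ± 105 CPM in ST6KO (n = 2 and n = 3, SD), GSTP1, a glutathione transferase, at 106 ± 51.3 against 284 ± 18.7 CPM, and the tubulin gene TUBB2A at 9.51 ± 0.315 against 27.1 ± 2.21 CPM. Their list had 3 of 21 tested members higher and 1 lower and was not called as a set (camera adjusted p = 0.56). Among matrix proteases and their inhibitors, DESeq2 called 1 of 26 higher and 5 lower (camera adjusted p = 0.567), with MMP16, a membrane-bound metalloproteinase, at 30.7 ± 12.1 against 3.05 ± 3.14 CPM and ADAM19 at 84.9 ± 7.83 against 36.1 ± 6.75 CPM. By edgeR, the log2 fold change of CYP1B1 was 2.47, or 1.86 without ST6WT replicate 1, 3.54 without ST6WT replicate 2 and 1.86 without ST6KO replicate 1. That of GSTP1 was 1.42, or 2.02 without ST6WT replicate 2, and that of MMP16 −3.33, or −4.61 without ST6KO replicate 2.

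Targets of TGF-beta and BMP signalling had 1 of 20 members higher and 3 lower by DESeq2 (camera adjusted p = 0.323, or 8.8e-05 without ST6WT replicate 1). ID1 and ID3, inhibitors of helix-loop-helix factors, differed between the ST6WT clones themselves, at 67.6 and 353 CPM for ID1 and 17.6 and 104 CPM for ID3, while the ST6KO clones lay between 25.1 and 36.7 CPM and between 9.75 and 10.2 CPM. Their log2 fold changes by edgeR were −2.77 and −2.59, or −1.14 and −0.81 without ST6WT replicate 2 and −3.52 and −3.37 without ST6WT replicate 1, and without ST6KO replicate 2 DESeq2 called neither (adjusted p = 0.09 and 0.122). In the glycolysis list, GAPDH, often used as a reference gene, was at 2998 ± 207 CPM in ST6WT and 1606 ± 208 CPM in ST6KO (log2 fold change −0.92 ± 0.20, DESeq2 adjusted p = 0.000312, or 0.113 with chromosome medians removed), with camera giving the list an adjusted p of 0.505. Of apoptosis regulators, 4 of 32 were called higher and 1 lower by DESeq2 (camera adjusted p = 0.265), among them CFLAR, an inhibitor of caspase-8 activation, at 60.2 ± 10.2 against 107 ± 9.82 CPM (adjusted p = 0.322 with chromosome medians removed), and TNFRSF10D, a decoy receptor for TRAIL, at 140 ± 50.2 against 49.1 ± 13.5 CPM.

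The median change of a chromosome's genes differed between chromosomes, and whether whole chromosomes or parts of them shifted was not tested. The median log2 fold change was 0.43 over 462 genes of chromosome X, 0.36 over chromosome 7, 0.28 over chromosome 2 and −0.36 over 794 genes of chromosome 12, where DESeq2 called 76 genes lower and 7 higher. GAPDH, DUSP6, GALNT6 and PRIM1 lie on chromosome 12, and L1CAM and EBP on X. NEU1, HLA-B, HLA-C and HLA-F lie on chromosome 6 (median 0.20, with 39 genes called higher and 10 lower by DESeq2). NEU1 and these HLA genes stayed called by DESeq2 with chromosome medians removed, as did TUBB2A, SPDEF and NFKBIE on the same chromosome. SLC17A5 and CDKN1A, also on chromosome 6, did not (DESeq2 adjusted p = 0.0505 and 0.0984). A shift of a part of chromosome 6 was not tested. Medians of 12 of the 23 chromosomes lay outside the range of 1000 random gene sets of the same size, 11 of them with no overlap between the groups. These 12 were picked by their difference between the groups, so lack of overlap was likely among them. None of the other chromosomes lacked overlap, so the 20% that chance gives is to be set against 11 of all 23. Over the genes not called by DESeq2, the SD of the chromosome medians was 0.16, and the highest of 1000 shuffles gave 0.05. Genes of a chromosome are not independent, and what shifts them was not tested. With each library's chromosome medians removed, DESeq2 no longer called GAPDH (log2 fold change −0.92 ± 0.20 before, −0.57 ± 0.22 after), PRIM1 (−1.08 ± 0.33, −0.75 ± 0.29), PKP2 (−1.27 ± 0.34, −0.92 ± 0.35), EBP (1.01 ± 0.30, 0.63 ± 0.29), CFLAR (0.82 ± 0.23, 0.53 ± 0.26), CDKN1A (1.27 ± 0.41, 1.07 ± 0.39), SLC17A5 (1.15 ± 0.27, 0.93 ± 0.31), ST3GAL1 (−1.11 ± 0.36, −0.99 ± 0.34) and LAMA3 (−0.82 ± 0.20, −0.66 ± 0.35), as the changes became smaller and, for LAMA3, SLC17A5, CFLAR, GAPDH and PKP2, the SE larger.

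The genes called by edgeR without ST6KO replicate 2 were looked up in that library. Of 680 such genes, 546 (80.3%) differed from ST6WT in the same direction there. In 20 simulations of unchanged groups that share the ST6WT libraries, 81.7% of as many top-ranked genes did so (79.1% to 84.3%), so the pooled share in ST6KO replicate 2 was no higher than the shared controls give. By direction, 300 of 347 genes called higher (86.5%, simulated 79.8% to 87.6%) and 246 of 333 called lower (73.9%, simulated 77% to 84.6%) did so, the latter below the simulated range. Median log2 ratios in that library were 0.73 for genes called higher (1.60 without it) and −0.94 for genes called lower (−2.52 without it).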
